A study of Arabidopsis thaliana with 23 samples.

How the data were processed

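RNA was measured in germinating Arabidopsis thaliana seeds, whose tissue the labels give as embryo. Per the labels, seeds were stratified for 48 h at 4 degrees in the dark on medium with 3% sucrose, moved to continuous light at 22 degrees, and collected after 12 h, 24 h and 48 h of light. Of the 23 samples, 17 were bulk RNA libraries, made from intact or from dissociated material (tissue taken apart into cells), and 6 were single-cell samples. The groups held 3 bulk libraries each, except for 2 of dissociated material at 48 h, and 2 single-cell samples per time. The protocol text names the accessions Col-0 and Cvi-0, and the bulk sample descriptions begin with col. The labels speak of biological replicates but do not say whether these were separate sowings, so p-values measure the spread between samples.

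The deposited bulk table held raw read counts per locus, and per the labels the libraries were stranded total RNA with ribosomal RNA depletion. For the series as a whole the labels name Trim Galore 0.4.5, HISAT2 2.1.0, featureCounts, Cell Ranger 1.3.0, STAR and the TAIR10 genome build, without saying which tool served which data. The strand setting and read filters are not given in the sources used here. The deposited single-cell matrix held UMI counts (unique molecular identifiers, 1 per captured transcript) per gene and cell from a droplet 3 prime library. It held 12798 cells and 13501 genes, so genes and cells had been selected before deposit by rules not given in the sources used here. Deposited lists of kept barcodes tied each cell to its sample. The deposited table of cells also gave a cluster number from 1 to 15 and map coordinates, with no method stated. Its size factor, which the deposited header names as such and which is a ratio, was unrelated to the cells' UMI totals (Spearman correlation across cells from -0.0186 to 0.0235 within samples) and was not used.

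Single-cell sample totals ran from 400911 to 22843460 UMI. Of 37336 loci in the bulk table, 10173 had no count in any library and 20227 passed the filter on low counts. Gene names alone came from a reference table of the TAIR10.1 assembly, with an entry for 37051 of the loci.

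Bulk counts were fitted in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, low counts removed by filterByExpr on the 6 groups), with 1 mean per group and the spread shared over all 17 libraries. Its common coefficient of biological variation was 25.2%. Contrasts were dissociated minus intact at each time, later minus earlier within each material, and the difference of the dissociation effect between neighbouring times. The p-values took both directions and were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are CPM (counts scaled to a common total, after TMM), as mean ± SD over libraries. Fold changes are log2 values ± SE.

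The single-cell counts were summed over all cells of each sample and fitted in the same way on 10616 genes. A test within each named cell class was planned for classes with at least 20 cells in all 4 samples of a step. No class that could be named met this. Clusters 1 and 11 did, 1 for each step, and their tests were added after the data were seen. No doublet caller was run and no ambient RNA was removed. Shares of cells per cluster carry exact Clopper-Pearson 95% intervals, which cover counting error only. The smallest p that 2 samples against 2 can reach in an exact permutation test is 0.333, so shares were not tested.

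Gene lists, tests, contrasts and the rule for named genes were fixed before the data were examined. The 12 pathway lists covered detoxification, touch and defence, low oxygen, heat shock, jasmonate and wounding, seed storage proteins, late embryogenesis abundant (LEA) proteins and abscisic acid, gibberellin and cell wall loosening, photosynthesis, lipid mobilisation, ribosomes and the cell cycle. The 17 cell type lists covered epidermis, root hair, non-hair root epidermis, root cap, cortex, endodermis, procambium, phloem, xylem, shoot meristem, root meristem, cotyledon mesophyll, stomatal lineage, myrosin cell, dividing cell, endosperm and seed coat. The lists held 338 distinct loci, and 13 entries were left out because the reference gave another name. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, and again with an estimated correlation), adjusted over the pathway lists or the cell type lists of a comparison. The run with an estimated correlation also takes its degrees of freedom from the few libraries, so it is stricter even where the estimate is near 0.01.

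The text names, per comparison, the 6 largest rises and 6 largest falls among called nuclear genes with a symbol, a mean of at least 10 CPM and no overlap between the libraries of the groups. It also draws on the 2 called members with the largest change and the member with the highest level of each pathway list. For differences of effects the numbers were 4 and 4, without the condition on overlap. Any other gene is said to have been chosen after its values were seen.

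Clusters were named only by the lists, by a rule set after the data were seen. A marker with at least 10 UMI counted as detected. It peaked in a cluster when its level over all times was highest there and at least 2 times its mean over the other clusters (log2 of at least 1, with 20 CPM added to both). A name needed at least 3 peaking markers of a list, and more than of any other list. Clusters whose cells had a median under 0.333 of their samples' median UMI, without a marker of that list among their 10 leading genes, were to stay unnamed, and this left out none that met the first conditions.

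Whether replicate numbers pair samples was checked by correlating each library's deviations from its group mean over 11937 genes. Libraries of equal number correlated between 12 h and 24 h in intact material (0.159, 0.112 and 0.147) and in dissociated material (0.618, 0.499 and 0.331). From 24 h to 48 h the values were 0.438, 0.0564 and -0.0825 in intact and -0.0639 and -0.261 in dissociated material, and between materials 0.194, 0.0908 and 0.3496 at 12 h, 0.0795, 0.118 and 0.405 at 24 h and 0.489 and 0.406 at 48 h. Single-cell samples of equal number correlated as well (0.593, 0.672 and 0.422 over 2802 genes), and cells of equal replicate number shared a barcode prefix. Counts with replicate as a block are therefore given beside the single-cell results and where they moved a bulk count by over 1.5 times.

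Tests on simulated data had 200 genes changed at the observed spread. For dissociation at 12 h, on 20227 genes, 78.8% of genes changed by a log2 of 2 were recovered, with 6 false calls. For the 48 h contrast the share was 75.8% with 8 false calls, and for the difference between 12 h and 24 h it was 56.1% with 3. Camera found the planted list at 12 h (adjusted p = 1.21e-35) and called 0 of the others. This does not test its preset correlation. In sums of single cells over 10616 genes, a log2 of 4 was recovered for 63.6% of genes between 12 h and 24 h and for 77.3% between 24 h and 48 h, and a log2 of 2 for 4.48% and 8.96%.

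Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, an added fold of at least 2, a replicate block, fits on the compared groups alone, removal of plastid and mitochondrial genes, and leaving out each library. Leaving out both dissociated libraries numbered 1 at 12 h and 24 h, with and without the block, was added after the data were seen. Tables were handled with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. Dissociated bulk replicate 3 of 48 h was not analysed here, since the table holds 2 libraries of that group.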

Results

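Bulk RNA of intact and dissociated germinating seeds and single cells of dissociated material were profiled at 12 h, 24 h and 48 h of light. Bulk totals ran from 16068745 counts (dissociated, 12 h, replicate 1) to 28047987 (intact, 48 h, replicate 1). The 10 most abundant genes took 3.47% to 5.75% of a library's counts, and log2 levels of libraries of a group correlated at 0.954 to 0.994 across genes.

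The pair of 12 h single-cell samples held 352 and 1851 cells with median UMI totals of 848 and 726. At 24 h there were 698 and 3211 cells with medians of 1552 and 3982, and at 48 h 2018 and 4668 cells with medians of 2373.5 and 1449.5. Plastid transcripts took 5.68% of UMI in replicate 1 and 1.52% in replicate 2 at 24 h, 2.39% and 0.749% at 12 h, and 2.63% and 0.728% at 48 h.

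The first question was which transcripts the dissociation itself changed, beginning with seeds after 12 h of light (n = 3 each). The peroxidase gene PRX52 (AT5G05340) rose from 0.12 ± 0.0159 to 92.4 ± 44.3 CPM (log2 fold change 9.51 ± 0.97, adjusted p = 5.97e-06), and HRE2 (AT2G47520), for a transcription factor of the low-oxygen response, from 0.584 ± 0.318 to 109 ± 55.0 CPM (log2 fold change 7.54 ± 0.74, adjusted p = 3.83e-06). Among falls, SPX1 (AT5G20150), which acts in phosphate sensing, went from 265 ± 136 to 17.3 ± 6.24 CPM (log2 fold change -3.94 ± 0.53, adjusted p = 6.23e-05). The gibberellin synthesis gene GA3OX1 (AT1G15550) fell from 42.3 ± 4.44 to 3.01 ± 3.59 CPM (log2 fold change -3.83 ± 0.75, adjusted p = 9.66e-04). Of 20227 genes, 8679 were called, 3840 up and 4839 down, a balance that turned when the groups compared were fitted alone (3721 and 3105), without dissociated 12 h replicate 2 (3219 and 2989) and with no filter (4129 and 4092). The other rises in the largest 6 were CYP710A1, for a sterol desaturase, which had next to no counts in intact seeds (from 0.0144 ± 0.025 to 33.3 ± 25.4 CPM), GAD4, AOC2 and GSTU6, the last a glutathione transferase gene of a family whose members share reads, and AOC2 likewise has a close copy. The other falls were SLAH3, MYB34, G3Pp1 and MAPKKK20.

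The detoxification list rose with a median log2 fold change of 4.67 and adjusted p = 6.05e-18, but adjusted p = 0.0848 with an estimated correlation. Of 15 tested, 15 rose and 0 fell, over all genes and over the list alone. Touch and defence genes rose against other genes (median log2 fold change 0.54, adjusted p = 2.65e-04), but adjusted p = 0.0848 with an estimated correlation. Among 19 tested, calls up numbered 8 and calls down 1 over all genes, and 9 and 1 adjusted over the list alone. Low-oxygen genes had a median log2 fold change of 0.96 (adjusted p = 0.0239, rose), but adjusted p = 0.786 with an estimated correlation. Of 11 tested, 5 rose and 1 fell, over all genes and over the list alone. The gibberellin and cell wall, seed storage, heat shock, cell cycle, photosynthesis, jasmonate, ribosome, LEA and lipid mobilisation lists did not pass (adjusted p from 0.0843 to 0.862). The lists with median, mean and test of differing sign were LEA (median -0.08, mean -0.20, test up) and lipid mobilisation (median -0.04, mean -0.05, test up). The seed storage and gibberellin lists passed with a replicate block (adjusted p = 0.00743 and 0.0375) and without both dissociated libraries numbered 1 (0.0277 and 0.00644). The glutathione transferase gene GSTF8 (AT2G47730) had the highest level of the detoxification genes and rose from 211 ± 25.01 to 6334 ± 2620.1 CPM (log2 fold change 4.91 ± 0.33, adjusted p = 1.11e-07). The zinc-finger gene ZAT12 (AT5G59820), which many stresses induce, rose from 25.5 ± 7.34 to 1049 ± 115 CPM (log2 fold change 5.36 ± 0.49, adjusted p = 2.46e-06), while the touch gene TCH4 was not called (log2 fold change 0.14 ± 0.29, adjusted p = 0.721 with overlapping libraries).

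At 24 h the same question gave fewer calls (n = 3 each). The glutamate decarboxylase gene GAD4 (AT2G02010) rose from 0.988 ± 0.465 to 204 ± 161 CPM (log2 fold change 7.67 ± 1.26, adjusted p = 9.13e-04). MAPKKK18 (AT1G05100), for a kinase in abscisic acid signalling, rose from 1.31 ± 0.346 to 69.5 ± 16.2 CPM (log2 fold change 5.73 ± 0.29, adjusted p = 2.16e-08). The abscisic acid receptor gene PYL6 (AT2G40330) fell from 23.7 ± 8.72 to 3.47 ± 0.796 CPM (log2 fold change -2.77 ± 0.43, adjusted p = 5.64e-04), and the anion channel gene SLAH3 (AT5G24030) fell from 64.2 ± 27.5 to 10.97 ± 7.14 CPM (log2 fold change -2.55 ± 0.53, adjusted p = 0.00482). There were 2987 calls, 1963 up and 1024 down. The count hung on single libraries, since it was 1916 without intact 24 h replicate 1, 1771 without intact 24 h replicate 2, 4527 without dissociated 24 h replicate 1, 1303 without dissociated 24 h replicate 2 and 1325 without dissociated 24 h replicate 3. With both dissociated libraries numbered 1 at 12 h and 24 h left out, a step added after the data were seen, it was 5421.

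For the detoxification list the median log2 fold change was 2.95 with adjusted p = 7.76e-21 (rose), but adjusted p = 0.0739 with an estimated correlation. Of 15 tested, 13 rose and 0 fell, over all genes and over the list alone. The touch and defence list rose with a median log2 fold change of 0.402 and adjusted p = 6.52e-04, but adjusted p = 0.0739 with an estimated correlation. Of its 19 tested members, 7 rose and 1 fell over all genes, and 8 and 1 did so adjusted over the list alone. Seed storage genes fell against other genes (median log2 fold change -1.13, adjusted p = 0.00333), but adjusted p = 0.669 with an estimated correlation. Of 12 tested, 0 were called over all genes or over the list alone. Gibberellin and cell wall genes had a median log2 fold change of -0.92 (adjusted p = 0.00458, fell), but adjusted p = 0.669 with an estimated correlation. With 18 members tested, 0 rose and 4 fell over all genes, and 0 and 7 adjusted over the list alone. For the heat shock list the median log2 fold change was 1.53 with adjusted p = 0.0146 (rose), but adjusted p = 0.669 with an estimated correlation. There were 2 rises and 0 falls over all genes among 12 tested, and 3 and 0 adjusted over the list alone. The photosynthesis list fell with a median log2 fold change of -0.34 and adjusted p = 0.0218, but adjusted p = 0.669 with an estimated correlation. Of its 30 tested members, 1 rose and 2 fell over all genes, and 1 and 1 did so adjusted over the list alone. The ribosome, cell cycle, jasmonate, lipid mobilisation, low-oxygen and LEA lists did not pass (adjusted p from 0.0804 to 0.979). The lists with median, mean and test of differing sign were lipid mobilisation (median -0.06, mean 0.03, test up), low-oxygen (median -0.54, mean 0.26, test down) and LEA (median -0.02, mean -0.11, test up). Without both dissociated libraries numbered 1, photosynthesis had adjusted p = 0.0598 and ribosomes 0.00421. GSTF8 rose from 307 ± 27.8 to 2366 ± 820.1 CPM (log2 fold change 2.95 ± 0.30, adjusted p = 2.03e-05) and ZAT12 from 47.8 ± 21.5 to 579 ± 11.2 CPM (log2 fold change 3.60 ± 0.45, adjusted p = 1.09e-04).

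At 48 h, 2 dissociated libraries stood against 3 intact ones. WRKY28 (AT4G18170), a transcription factor gene, rose from 0.599 ± 0.221 to 97.7 ± 61.6 CPM (log2 fold change 7.34 ± 1.06, adjusted p = 1.46e-04), and ABCG40 (AT1G15520), for a transporter of abscisic acid, from 4.13 ± 1.01 to 379 ± 237 CPM (log2 fold change 6.53 ± 0.85, adjusted p = 6.42e-05). The extensin gene EXT12 (AT4G13390) fell from 23.57 ± 11.6 to 0.456 ± 0.0363 CPM (log2 fold change -5.67 ± 0.62, adjusted p = 3.20e-05), although extensins hold repeats and reads can be shared between them, and the xyloglucan enzyme gene XTH14 (AT4G25820) fell from 20.3 ± 15.6 to 1.24 ± 0.45 CPM (log2 fold change -4.05 ± 0.68, adjusted p = 4.30e-04). Calls numbered 6592, with 3672 up and 2920 down. RLE scaling, which moved the median of all genes by -0.12 in log2, gave 2945 up and 3708 down, and no filter 2633 and 3772, so the balance was not firm. The count was 2915 without dissociated 48 h replicate 1 and 4320 without dissociated 48 h replicate 2.

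Detoxification genes rose against other genes (median log2 fold change 3.16, adjusted p = 4.24e-12), but adjusted p = 0.365 with an estimated correlation. Of 15 tested, 14 rose and 0 fell, over all genes and over the list alone. Cell cycle genes had a median log2 fold change of -0.56 (adjusted p = 0.00121, fell), but adjusted p = 0.697 with an estimated correlation. Of 28 tested, 0 rose and 8 fell, over all genes and over the list alone. For the heat shock list the median log2 fold change was 2.63 with adjusted p = 0.00544 (rose), but adjusted p = 0.744 with an estimated correlation. There were 8 rises and 0 falls over all genes among 12 tested, and 9 and 0 adjusted over the list alone. The gibberellin and cell wall, LEA, low-oxygen, touch and defence, jasmonate, seed storage, photosynthesis, lipid mobilisation and ribosome lists did not pass (adjusted p from 0.0525 to 0.608). Calls of 3 heat shock genes rested on dissociated 48 h replicate 2. HSP17.6II (AT5G12020) rose from 2.97 ± 1.90 to 256 ± 329.7 CPM (log2 fold change 6.43 ± 1.199, adjusted p = 9.43e-04) but had adjusted p = 0.0558 without that library, and adjusted p was 0.122 for HSP17.4 and 0.271 for HSP70. Without intact 48 h replicate 1, HSP70 had adjusted p = 0.0701. The abscisic acid regulator gene ABI5 (AT2G36270) rose from 41.0 ± 3.32 to 309 ± 94.8 CPM (log2 fold change 2.91 ± 0.18, adjusted p = 1.00e-07). RLE scaling turned the sign of the medians of the lipid mobilisation and ribosome lists, which did not pass under either, and LEA genes passed with it (adjusted p = 0.0478). The gibberellin list passed with the block (0.0289) and without both first dissociated libraries (0.0241).

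**Figure D1:**
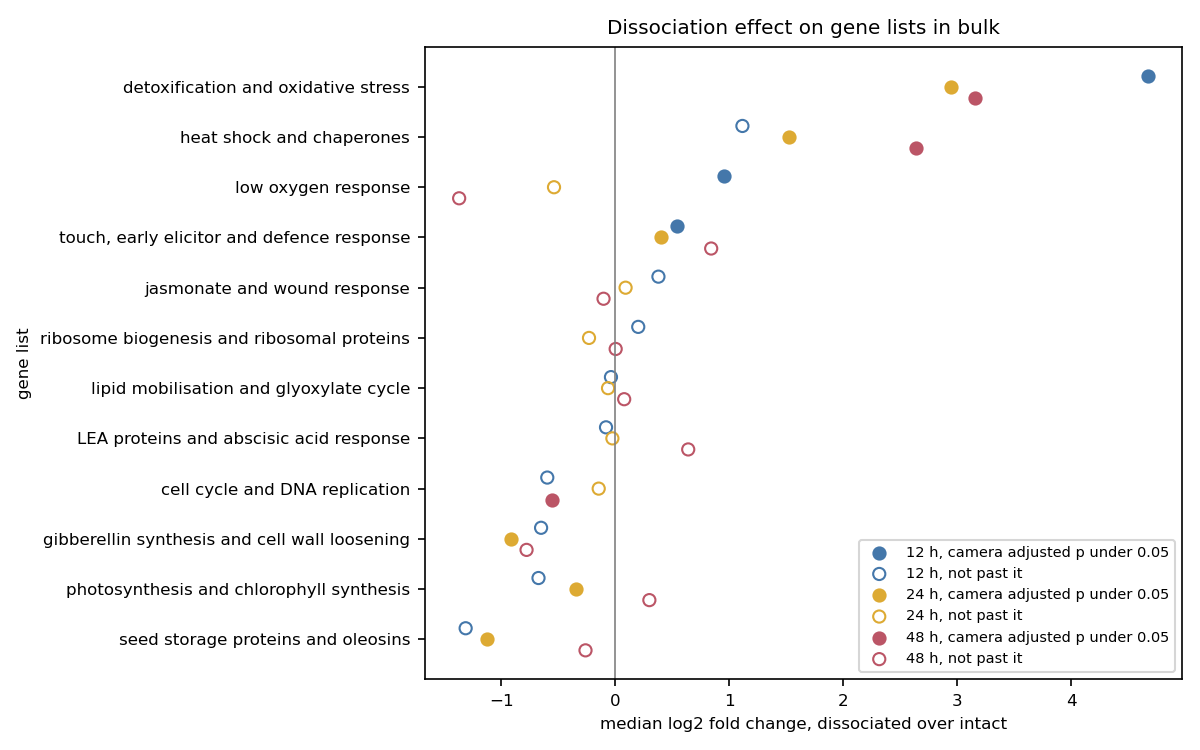
Median log2 fold change of dissociated over intact bulk material (horizontal axis) for the 12 pathway lists at 12 h, 24 h and 48 h, with filled points where the camera test passed. The detoxification list lay farthest right at each time, with medians of 4.67, 2.95 and 3.16.

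The times were then compared for shared calls. The genes called up at 12 h and at 24 h shared 1736 members, 4.66 times the number that independent lists would share, and the genes called down shared 861, or 3.51 times. Between 24 h and 48 h the shared genes were 1692 up and 680 down (4.75 and 4.60 times), and between 12 h and 48 h 2358 and 1811 (3.38 and 2.59 times). All times together shared 1532 genes up and 602 down, where independent lists would share 67.7 and 35.4. Genes up at all times made up 5.92% to 7.76% of CPM in intact libraries and 12.2% to 27.0% in dissociated ones. Genes are not independent of one another, so no p-value is given for these overlaps.

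Whether the effect of dissociation changed with time was tested by the difference of effects. Between 12 h and 24 h, edgeR called 1 gene of 20227 (2936 had an unadjusted p under 0.05), DESeq2 called 309, and the fit with a replicate block 3. With both dissociated libraries numbered 1 left out the count was 828, and 2098 with the block added. The gene, AT5G22140, was named after its values were seen, and fitted on the compared groups alone it was not called. Its rise of 6.82 in log2 at 12 h was 3.42 at 24 h, a difference of -3.40 (adjusted p = 0.0444). The count was 1208 without dissociated 12 h replicate 1, and 0 without any single intact 12 h library, dissociated 12 h replicate 2 or 3, intact 24 h replicate 1 or 2, or dissociated 24 h replicate 1 or 3. The low-oxygen list had a lower dissociation effect at 24 h (median log2 difference -1.40, adjusted p = 7.67e-07), but adjusted p = 0.345 with an estimated correlation. Of its 11 tested members, 0 had a higher and 0 a lower effect over all genes, and 0 and 6 did so adjusted over the list alone. Detoxification genes had a lower effect at 24 h (median log2 difference -1.33, adjusted p = 9.69e-07), but adjusted p = 0.3998 with an estimated correlation. Among 15 tested, calls up numbered 0 and calls down 0 over all genes, and 0 and 4 adjusted over the list alone. Ribosome genes had a median log2 difference of -0.35 (adjusted p = 4.66e-04, lower effect at 24 h), but adjusted p = 0.715 with an estimated correlation. Of 19 tested, 0 were called over all genes or over the list alone. For the touch and defence list the median log2 difference was -0.27 with adjusted p = 0.0161 (lower effect at 24 h), but adjusted p = 0.345 with an estimated correlation. Of 19 tested, 0 were called over all genes or over the list alone. The jasmonate, cell cycle, LEA, heat shock, seed storage, photosynthesis, lipid mobilisation and gibberellin and cell wall lists did not pass (adjusted p from 0.142 to 0.985). The lists with median, mean and test of differing sign were LEA (median -0.09, mean 0.09, test down), seed storage (median 0.21, mean 0.23, test down), photosynthesis (median 0.15, mean 0.03, test down) and gibberellin and cell wall (median 0.12, mean -0.44, test up).

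Between 24 h and 48 h, edgeR called 9 genes (7 up and 2 down, with 2269 at an unadjusted p under 0.05), DESeq2 called 300 (117 up and 183 down), and the fit with a replicate block called 20. The dissociation effect on ABI5 grew from 0.94 to 2.91 in log2, a difference of 1.97 ± 0.24 (adjusted p = 0.00524), with adjusted p = 0.124 without dissociated 48 h replicate 1 and 0.103 when the groups compared were fitted alone. That on UGT78D2 (AT5G17050), for a flavonoid glycosyltransferase, went from 0.38 to -1.32, a difference of -1.70 ± 0.21 (adjusted p = 0.00524, or 0.0609 when the groups compared were fitted alone). RLE scaling moved the median of all genes by -0.13 and left 4 calls. The count was 2 without intact 24 h replicate 1 or intact 24 h replicate 3 or dissociated 48 h replicate 1, 43 without intact 24 h replicate 2, 5 without dissociated 24 h replicate 2, 4 without intact 48 h replicate 2, 3 without intact 48 h replicate 3 and 25 without dissociated 48 h replicate 2. The cell cycle list fell with a median log2 fold change of -0.64 and adjusted p = 2.02e-06, but adjusted p = 0.406 with an estimated correlation. Of its 28 tested members, 0 rose and 0 fell over all genes, and 0 and 2 did so adjusted over the list alone. Photosynthesis genes rose against other genes (median log2 fold change 0.66, adjusted p = 2.89e-04), but adjusted p = 0.465 with an estimated correlation. Of 30 tested, 0 were called over all genes or over the list alone. LEA genes had a median log2 fold change of 0.67 (adjusted p = 0.00215, rose), but adjusted p = 0.582 with an estimated correlation. With 18 members tested, 1 rose and 0 fell over all genes, and 5 and 0 adjusted over the list alone. For the low-oxygen list the median log2 fold change was -0.53 with adjusted p = 0.00376 (fell), but adjusted p = 0.582 with an estimated correlation. There were 0 rises and 0 falls over all genes among 11 tested, and 0 and 1 adjusted over the list alone. The heat shock list had a higher effect at 48 h (median log2 difference 0.94, adjusted p = 0.0393), but adjusted p = 0.684 with an estimated correlation. Of 12 tested, 0 were called over all genes or over the list alone. Seed storage genes rose against other genes (median log2 fold change 0.88, adjusted p = 0.0398), but adjusted p = 0.711 with an estimated correlation. Of 12 tested, 0 were called over all genes or over the list alone. Touch and defence genes had a median log2 fold change of -0.34 (adjusted p = 0.0467, fell), but adjusted p = 0.465 with an estimated correlation. Of 19 tested, 0 were called over all genes or over the list alone. The jasmonate, ribosome, gibberellin and cell wall, lipid mobilisation and detoxification lists did not pass (adjusted p from 0.0866 to 0.773). The touch and defence list had adjusted p = 0.0634 with RLE scaling and 0.112 with the block. Without both dissociated libraries numbered 1, heat shock had adjusted p = 0.1097, jasmonate 0.012 and ribosomes 0.0074. RLE scaling turned the sign of the medians of the detoxification, gibberellin and lipid mobilisation lists.

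Intact seeds were next compared from 12 h to 24 h (n = 3 each). The early light-induced gene ELIP1 (AT3G22840) rose from 1.52 ± 0.406 to 45.7 ± 18.6 CPM (log2 fold change 4.91 ± 0.43, adjusted p = 6.79e-06). APE2 (AT5G46110), for a chloroplast triose phosphate transporter, rose from 4.08 ± 0.755 to 55.4 ± 12.7 CPM (log2 fold change 3.76 ± 0.24, adjusted p = 8.34e-07), and TT4 (AT5G13930), for chalcone synthase, from 1.28 ± 1.08 to 37.6 ± 32.4 CPM (log2 fold change 4.91 ± 0.67, adjusted p = 2.52e-04). GA3OX1 fell from 42.3 ± 4.44 to 4.03 ± 2.11 CPM (log2 fold change -3.39 ± 0.72, adjusted p = 0.00573), and the seed protein gene M10 (AT2G41280) from 299 ± 229 to 43.8 ± 29.7 CPM (log2 fold change -2.77 ± 0.53, adjusted p = 0.00307). Of 3150 calls, 1732 were up and 1418 down. The count was 1874 without intact 12 h replicate 1, 1833 without intact 12 h replicate 2, 1951 without intact 12 h replicate 3 and 1795 without intact 24 h replicate 1.

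For the photosynthesis list the median log2 fold change was 2.02 with adjusted p = 2.08e-40 (rose), and held with adjusted p = 0.00178 with an estimated correlation. There were 23 rises and 0 falls over all genes among 30 tested, and 25 and 0 adjusted over the list alone. The cell cycle list rose with a median log2 fold change of 0.60 and adjusted p = 7.32e-05, but adjusted p = 0.414 with an estimated correlation. Of its 28 tested members, 6 rose and 0 fell over all genes, and 9 and 0 did so adjusted over the list alone. Seed storage genes fell against other genes (median log2 fold change -1.80, adjusted p = 8.62e-04), but adjusted p = 0.639 with an estimated correlation. Among 12 tested, calls up numbered 0 and calls down 4 over all genes, and 0 and 10 adjusted over the list alone. Low-oxygen genes had a median log2 fold change of 0.86 (adjusted p = 0.00442, rose), but adjusted p = 0.639 with an estimated correlation. With 11 members tested, 1 rose and 0 fell over all genes, and 2 and 0 adjusted over the list alone. For the lipid mobilisation list the median log2 fold change was 0.28 with adjusted p = 0.00679 (rose), but adjusted p = 0.639 with an estimated correlation. Of 19 tested, 5 rose and 0 fell, over all genes and over the list alone. The ribosome, detoxification, gibberellin and cell wall, jasmonate, LEA, touch and defence and heat shock lists did not pass (adjusted p from 0.0997 to 0.988). The lists with median, mean and test of differing sign were ribosome (median 0.06, mean -0.22, test down), detoxification (median 0.12, mean -0.28, test down) and heat shock (median 0.19, mean -0.00, test down). The small Rubisco subunit gene RBCS1A (AT1G67090) rose from 379.5 ± 56.2 to 1789 ± 294 CPM (log2 fold change 2.24 ± 0.22, adjusted p = 1.49e-05), and the Calvin cycle gene PRK (AT1G32060) from 1.79 ± 0.758 to 23.8 ± 8.08 CPM (log2 fold change 3.74 ± 0.35, adjusted p = 9.24e-06).

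In dissociated material the same step (n = 3 each) gave 4481 calls, 2588 up and 1893 down. FTM1 (AT1G43800), of the fatty acid desaturase family, rose from 1.45 ± 0.173 to 81.3 ± 19.2 CPM (log2 fold change 5.81 ± 0.44, adjusted p = 1.31e-06), PRK from 0.653 ± 0.38 to 21.7 ± 2.08 CPM (log2 fold change 5.01 ± 0.397, adjusted p = 2.20e-06) and APE2 from 3.28 ± 0.994 to 58.5 ± 6.96 CPM (log2 fold change 4.15 ± 0.24, adjusted p = 3.21e-07). The glutathione transferase gene GSTF2 (AT4G02520) fell from 104 ± 51.1 to 9.21 ± 1.77 CPM (log2 fold change -3.50 ± 0.60, adjusted p = 0.00106), and DMR6 (AT5G24530), which acts against defence, from 41.0 ± 23.59 to 3.77 ± 1.13 CPM (log2 fold change -3.44 ± 0.47, adjusted p = 2.09e-04). The count was 2714 without dissociated 12 h replicate 2, and 1527 when the groups compared were fitted alone. The photosynthesis list rose with a median log2 fold change of 2.01 and adjusted p = 6.75e-31, and held with adjusted p = 0.00445 with an estimated correlation. Of 30 tested, 24 rose and 0 fell, over all genes and over the list alone. Cell cycle genes rose against other genes (median log2 fold change 1.05, adjusted p = 1.67e-06), but adjusted p = 0.244 with an estimated correlation. Among 28 tested, calls up numbered 14 and calls down 0 over all genes, and 17 and 0 adjusted over the list alone. Detoxification genes had a median log2 fold change of -1.43 (adjusted p = 1.67e-06, fell), but adjusted p = 0.398 with an estimated correlation. With 15 members tested, 0 rose and 8 fell over all genes, and 0 and 9 adjusted over the list alone. For the ribosome list the median log2 fold change was -0.48 with adjusted p = 2.35e-06 (fell), but adjusted p = 0.398 with an estimated correlation. There were 0 rises and 6 falls over all genes among 19 tested, and 0 and 10 adjusted over the list alone. The seed storage list fell with a median log2 fold change of -1.42 and adjusted p = 1.92e-04, but adjusted p = 0.398 with an estimated correlation. Of 12 tested, 0 rose and 3 fell, over all genes and over the list alone. Lipid mobilisation genes rose against other genes (median log2 fold change 0.29, adjusted p = 0.00891), but adjusted p = 0.398 with an estimated correlation. Among 19 tested, calls up numbered 6 and calls down 0 over all genes, and 8 and 0 adjusted over the list alone. The touch and defence, low-oxygen, LEA, jasmonate, gibberellin and cell wall and heat shock lists did not pass (adjusted p from 0.105 to 0.571).

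From 24 h to 48 h in intact seeds (n = 3 each), the extensin genes EXT10 (AT5G06640) and EXT6 (AT2G24980) had 0 counts in all 24 h libraries and 34.01 ± 14.4 and 30.5 ± 14.3 CPM at 48 h. The xyloglucan enzyme gene XTH7 (AT4G37800) went likewise from 0 ± 0 to 25.5 ± 17.5 CPM. CDC20.1 (AT4G33270), an activator of mitotic exit, rose from 0.3003 ± 0.179 to 21.6 ± 2.48 CPM (log2 fold change 6.13 ± 0.48, adjusted p = 4.87e-07). The sieve element gene SEOR1 (AT3G01680) fell from 34.7 ± 6.87 to 2.71 ± 0.552 CPM (log2 fold change -3.68 ± 0.36, adjusted p = 2.69e-06), and the storage albumin gene SESA4 (AT4G27170), which shares reads with its neighbours, from 328 ± 52.4 to 35.7 ± 3.38 CPM (log2 fold change -3.20 ± 0.63, adjusted p = 0.00111). Calls numbered 7673, 3851 up and 3822 down. RLE scaling moved the median of all genes by 0.13 and gave 4478 up and 2652 down.

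Cell cycle genes had a median log2 fold change of 1.33 (adjusted p = 1.67e-19, rose), and held with adjusted p = 0.0138 with an estimated correlation. With 28 members tested, 21 rose and 0 fell over all genes, and 24 and 0 adjusted over the list alone. For the LEA list the median log2 fold change was -1.72 with adjusted p = 2.94e-06 (fell), but adjusted p = 0.294 with an estimated correlation. There were 0 rises and 12 falls over all genes among 18 tested, and 0 and 14 adjusted over the list alone. The jasmonate list rose with a median log2 fold change of 2.96 and adjusted p = 1.08e-05, but adjusted p = 0.115 with an estimated correlation. Of its 13 tested members, 11 rose and 0 fell over all genes, and 13 and 0 did so adjusted over the list alone. Photosynthesis genes rose against other genes (median log2 fold change 0.97, adjusted p = 3.32e-05), but adjusted p = 0.294 with an estimated correlation. Among 30 tested, calls up numbered 17 and calls down 3 over all genes, and 19 and 3 adjusted over the list alone. Seed storage genes had a median log2 fold change of -1.98 (adjusted p = 0.00139, fell), but adjusted p = 0.603 with an estimated correlation. With 12 members tested, 0 rose and 7 fell over all genes, and 0 and 9 adjusted over the list alone. For the ribosome list the median log2 fold change was -0.41 with adjusted p = 0.0192 (fell), but adjusted p = 0.72 with an estimated correlation. There were 0 rises and 7 falls over all genes among 19 tested, and 0 and 8 adjusted over the list alone. The gibberellin and cell wall list fell with a median log2 fold change of -0.76 and adjusted p = 0.0192, but adjusted p = 0.603 with an estimated correlation. Of its 18 tested members, 1 rose and 7 fell over all genes, and 1 and 7 did so adjusted over the list alone. The detoxification, low-oxygen, lipid mobilisation, touch and defence and heat shock lists did not pass (adjusted p from 0.154 to 0.68). Median, mean and test differed in sign for touch and defence (median -0.15, mean 0.17, test down). TSO2, for a ribonucleotide reductase subunit, rose from 52.5 ± 11.1 to 111 ± 26.2 CPM (log2 fold change 1.08 ± 0.25, adjusted p = 0.00326), and the jasmonate repressor gene JAZ1 (AT1G19180) from 96.3 ± 7.39 to 284 ± 12.8 CPM (log2 fold change 1.56 ± 0.398, adjusted p = 0.00638). The LEA gene LEA4-5 (AT5G06760) fell from 396 ± 59.7 to 123 ± 18.8 CPM (log2 fold change -1.69 ± 0.30, adjusted p = 5.51e-04).

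In dissociated material this step, with 3 libraries at 24 h and 2 at 48 h, gave 3565 calls, 2327 up and 1238 down. CDC20.1 rose from 0.542 ± 0.225 to 19.9 ± 5.72 CPM (log2 fold change 5.18 ± 0.47, adjusted p = 4.46e-06), and the cysteine protease gene CEP2 (AT3G48340), with few counts at 24 h, went from 0.0499 ± 0.0505 to 34.8 ± 13.6 CPM. The serine carboxypeptidase-like gene scpl44 (AT1G43780) fell from 303 ± 79.2 to 43.5 ± 16.001 CPM (log2 fold change -2.80 ± 0.31, adjusted p = 2.46e-05). The heat shock gene HSP17.6II rose (log2 fold change 3.34 ± 1.05, adjusted p = 0.0382 with overlapping libraries), but its sign turned to -0.17 (adjusted p = 0.949) without dissociated 48 h replicate 2, and adjusted p was 0.0946, 0.0785 and 0.0597 without dissociated 24 h replicates 1, 2 and 3. The count was 1624 without dissociated 48 h replicate 1 and 2016 without dissociated 48 h replicate 2.

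Photosynthesis genes rose against other genes (median log2 fold change 1.73, adjusted p = 8.83e-16), and held with adjusted p = 0.0313 with an estimated correlation. Among 30 tested, calls up numbered 20 and calls down 0 over all genes, and 22 and 0 adjusted over the list alone. Cell cycle genes had a median log2 fold change of 1.12 (adjusted p = 5.43e-15, rose), and held with adjusted p = 0.0313 with an estimated correlation. With 28 members tested, 15 rose and 1 fell over all genes, and 18 and 1 adjusted over the list alone. For the jasmonate list the median log2 fold change was 2.32 with adjusted p = 1.21e-04 (rose), but adjusted p = 0.13 with an estimated correlation. There were 4 rises and 0 falls over all genes among 13 tested, and 9 and 0 adjusted over the list alone. The LEA list fell with a median log2 fold change of -1.12 and adjusted p = 8.95e-04, but adjusted p = 0.432 with an estimated correlation. Of its 18 tested members, 0 rose and 6 fell over all genes, and 0 and 7 did so adjusted over the list alone. Gibberellin and cell wall genes fell against other genes (median log2 fold change -0.97, adjusted p = 0.00163), but adjusted p = 0.432 with an estimated correlation. Among 18 tested, calls up numbered 1 and calls down 6 over all genes, and 1 and 7 adjusted over the list alone. Seed storage genes had a median log2 fold change of -1.40 (adjusted p = 0.0217, fell), but adjusted p = 0.589 with an estimated correlation. Of 12 tested, 0 were called over all genes or over the list alone. For the detoxification list the median log2 fold change was 0.89 with adjusted p = 0.0276 (rose), but adjusted p = 0.589 with an estimated correlation. There were 3 rises and 0 falls over all genes among 15 tested, and 5 and 0 adjusted over the list alone. The touch and defence list fell with a median log2 fold change of -0.31 and adjusted p = 0.0276, but adjusted p = 0.28 with an estimated correlation. Of its 19 tested members, 0 rose and 4 fell over all genes, and 0 and 4 did so adjusted over the list alone. Heat shock genes rose against other genes (median log2 fold change 1.99, adjusted p = 0.0362), but adjusted p = 0.589 with an estimated correlation. Among 12 tested, calls up numbered 5 and calls down 0 over all genes, and 6 and 0 adjusted over the list alone. Ribosome genes had a median log2 fold change of -0.20 (adjusted p = 0.0444, fell), but adjusted p = 0.613 with an estimated correlation. Of 19 tested, 0 were called over all genes or over the list alone. The lipid mobilisation and low-oxygen lists did not pass (adjusted p from 0.222 to 0.861). Median, mean and test differed in sign for low-oxygen (median 0.31, mean 0.28, test down). Without both dissociated libraries numbered 1, 4 of these calls were lost, with adjusted p = 0.115 for detoxification, 0.16043 for heat shock, 0.436 for ribosomes and 0.334 for seed storage. Of all 61 pathway list calls in the 11 bulk and single-cell comparisons, 5 held with an estimated correlation. They were photosynthesis from 12 h to 24 h in both materials and from 24 h to 48 h in dissociated material, and the cell cycle from 24 h to 48 h in both. Jasmonate genes in cells from 24 h to 48 h lost their call at an estimate of 0.0125, near the preset 0.01. So correlation does not account for that loss, and other losses were not tested for it.

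**Figure D2:**
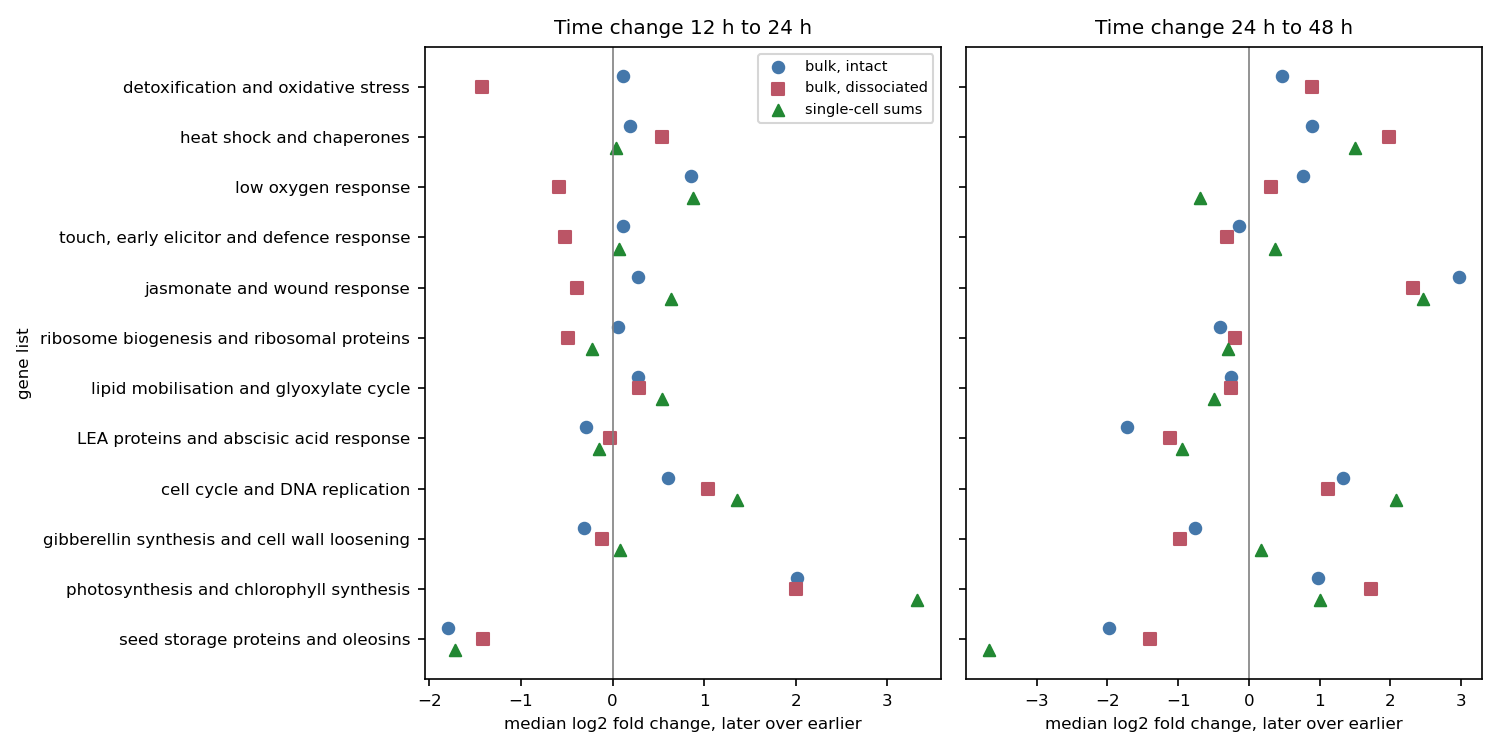
Median log2 fold change of later over earlier samples (horizontal axes) for the 12 pathway lists, left from 12 h to 24 h and right from 24 h to 48 h, in intact bulk, dissociated bulk and sums of single cells. Medians of the photosynthesis list from 12 h to 24 h were 2.02, 2.01 and 3.33, and those of the seed storage list from 24 h to 48 h were -1.98, -1.40 and -3.67.

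The cell type lists were tested in the same way, and brackets give the median log2 fold change, adjusted p and, with an estimated correlation, adjusted p, then members called up and down over all genes, those tested, and the calls adjusted over the list alone. From 12 h to 24 h in intact seeds, cotyledon mesophyll (1.73, 4.87e-14 and 0.00917, 7 and 0 of 11, 8 and 0), dividing cell (0.996, 0.00473 and 0.103, 4 and 0 of 10, 6 and 0) and xylem (0.71, 0.0288 and 0.0948, 3 and 0 of 12, 3 and 0) genes rose, while procambium (-0.43, 0.0458 and 0.566, 0 and 1 of 14, 0 and 1) genes fell, and phloem, shoot meristem, root hair cell, stomatal lineage, endodermis, root cap and epidermis did not pass (adjusted p from 0.0615 to 0.986). In dissociated material over this step, cotyledon mesophyll (1.88, 7.35e-08 and 0.0642, 8 and 0 of 11, 8 and 0) genes rose, and dividing cell, phloem, stomatal lineage, xylem, procambium, epidermis, shoot meristem, endodermis, root cap and root hair cell did not pass (adjusted p from 0.0756 to 0.649). From 24 h to 48 h in intact seeds, dividing cell (3.27, 5.99e-16 and 5.73e-04, 9 and 0 of 10, 9 and 0), root hair cell (8.79, 9.83e-12 and 0.0104, 7 and 0 of 7, 7 and 0), xylem (1.64, 3.44e-06 and 0.0017, 7 and 0 of 12, 7 and 0) and cotyledon mesophyll (2.31, 0.00176 and 0.176, 6 and 0 of 11, 9 and 0) genes rose, and endodermis, phloem, stomatal lineage, epidermis, procambium, root cap and shoot meristem did not pass (adjusted p from 0.0587 to 0.794). In dissociated material from 24 h to 48 h, dividing cell (2.51, 2.71e-16 and 6.85e-04, 8 and 0 of 10, 8 and 0), root hair cell (7.33, 1.28e-09 and 0.0121, 6 and 0 of 7, 6 and 0), cotyledon mesophyll (3.62, 2.43e-09 and 0.0121, 9 and 0 of 11, 10 and 0) and xylem (1.025, 1.56e-05 and 0.00313, 5 and 0 of 12, 5 and 0) genes rose, and shoot meristem, phloem, epidermis, endodermis, root cap, procambium and stomatal lineage did not pass (adjusted p from 0.201 to 0.968). In sums of single cells from 12 h to 24 h, cotyledon mesophyll (3.34, 3.01e-15 and 0.117, 0 and 0 of 11, 8 and 0) and dividing cell (1.35, 0.0266 and 0.493, 0 and 0 of 10, 1 and 0) genes rose, while procambium (-1.017, 0.0361 and 0.416, 0 and 0 of 9, 0 and 0) genes fell, and epidermis, root cap and phloem did not pass (adjusted p from 0.0867 to 0.799). In such sums from 24 h to 48 h, dividing cell (3.42, 4.49e-07 and 0.281, 6 and 0 of 10, 8 and 0), cotyledon mesophyll (2.97, 4.70e-05 and 0.281, 6 and 0 of 11, 7 and 0) and root cap (3.94, 0.0416 and 0.281, 2 and 0 of 5, 3 and 0) genes rose, and epidermis, phloem and procambium did not pass (adjusted p from 0.0624 to 0.654).

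With values in the same order, for dissociation at 12 h, procambium (-1.10, 0.033 and 0.832, 1 and 9 of 14, 2 and 9) genes fell, and epidermis, shoot meristem, stomatal lineage, xylem, root cap, dividing cell, endodermis, root hair cell, phloem and cotyledon mesophyll did not pass (adjusted p from 0.287 to 0.73). For dissociation at 24 h, procambium (-0.67, 0.00726 and 0.466, 1 and 4 of 14, 1 and 5), cotyledon mesophyll (-0.94, 0.0434 and 0.488, 0 and 1 of 11, 0 and 3), xylem (-0.81, 0.0434 and 0.203, 0 and 2 of 12, 0 and 2) and shoot meristem (-0.81, 0.0434 and 0.466, 0 and 0 of 7, 0 and 2) genes fell, and epidermis, stomatal lineage, endodermis, dividing cell, root hair cell, phloem and root cap did not pass (adjusted p from 0.286 to 0.844). For dissociation at 48 h, root hair cell (-3.11, 0.00313 and 0.353, 0 and 5 of 7, 0 and 5), xylem (-1.26, 0.00975 and 0.0788, 0 and 5 of 12, 0 and 6), shoot meristem (-1.99, 0.0211 and 0.359, 0 and 2 of 7, 0 and 6), epidermis (-0.71, 0.0335 and 0.384, 0 and 5 of 11, 0 and 5), stomatal lineage (-1.33, 0.0335 and 0.359, 0 and 3 of 8, 0 and 3) and endodermis (-2.09, 0.0428 and 0.359, 0 and 4 of 9, 0 and 4) genes fell, and phloem, dividing cell, procambium, cotyledon mesophyll and root cap did not pass (adjusted p from 0.071 to 0.906). For the difference of effects between 12 h and 24 h, no cell type list passed (adjusted p from 0.512 to 0.997). For that between 24 h and 48 h, cotyledon mesophyll (0.79, 0.00736 and 0.352, 0 and 0 of 11, 0 and 0) and phloem (0.90, 0.00736 and 0.352, 0 and 0 of 12, 1 and 0) genes had a higher effect later, while dividing cell (-0.44, 0.00736 and 0.331, 0 and 0 of 10, 0 and 1) and epidermis (-0.52, 0.0332 and 0.49, 0 and 0 of 11, 0 and 0) genes had a lower one, and stomatal lineage, shoot meristem, endodermis, procambium, xylem, root hair cell and root cap did not pass (adjusted p from 0.0683 to 0.689). Root hair genes had few or no counts before 48 h, so their median gives a direction and no size. Lists of cortex, endosperm, myrosin cell, non-hair root epidermis, root meristem and seed coat had under 5 tested members, and in cells so did those of endodermis, root hair cell, shoot meristem, stomatal lineage and xylem.

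Sums of single cells asked for the time course in the cells that were kept (n = 2 per time), and mix changes in expression with changes in which cells were caught. From 12 h to 24 h edgeR called 0 of 10616 genes, with 877 at an unadjusted p under 0.05, while DESeq2 called 260 and the fit with a replicate block 243. RBCS1A had the highest level of the photosynthesis genes and went from 1336 ± 6.93 to 11921 ± 4437 CPM (log2 fold change 3.16 ± 0.75, adjusted p = 0.337), which was not called. For the photosynthesis list the median log2 fold change was 3.33 with adjusted p = 1.37e-46 (rose), but adjusted p = 0.0749 with an estimated correlation. There were 0 rises and 0 falls over all genes among 26 tested, and 23 and 0 adjusted over the list alone. With a replicate block, 20 of them rose over all genes, as did 7 of 11 cotyledon mesophyll genes. The seed storage list fell with a median log2 fold change of -1.72 and adjusted p = 2.41e-09, but adjusted p = 0.304 with an estimated correlation. Of 12 tested, 0 were called over all genes or over the list alone. Cell cycle genes rose against other genes (median log2 fold change 1.35, adjusted p = 9.40e-05), but adjusted p = 0.556 with an estimated correlation. Of 24 tested, 0 were called over all genes or over the list alone. LEA genes had a median log2 fold change of -0.15 (adjusted p = 0.0328, fell), but adjusted p = 0.713 with an estimated correlation. Of 15 tested, 0 were called over all genes or over the list alone. The lipid mobilisation, jasmonate, low-oxygen, gibberellin and cell wall, heat shock, ribosome and touch and defence lists did not pass (adjusted p from 0.121 to 0.774). The lists with median, mean and test of differing sign were heat shock (median 0.04, mean -0.15, test down), ribosome (median -0.22, mean 0.05, test down) and touch and defence (median 0.07, mean -0.07, test down). With a replicate block the lipid mobilisation list passed (adjusted p = 0.0276). RLE scaling turned the median of the heat shock list.

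From 24 h to 48 h, 797 genes were called, 680 up and 117 down, against 1459 by DESeq2 and 3217 with a replicate block. The jasmonate synthesis gene OPR3 (AT2G06050) rose from 11.9 ± 4.52 to 133 ± 4.65 CPM (log2 fold change 3.43 ± 0.46, adjusted p = 0.0144), and CDC20.1 from 0.593 ± 0.11 to 53.1 ± 17.5 CPM (log2 fold change 6.56 ± 0.65, adjusted p = 0.0116). The seed protein gene M17 (AT2G41260) fell from 174 ± 69.4 to 1.92 ± 0.641 CPM (log2 fold change -6.51 ± 0.75, adjusted p = 0.0121), and the transcription factor gene NAP (AT1G69490) from 20.2 ± 2.98 to 0.73 ± 0.311 CPM (log2 fold change -4.81 ± 0.59, adjusted p = 0.0132). Each of these calls was lost without 24 h replicate 2, where the count was 0 and adjusted p was 0.065 for all 4. The count was 302 without the 24 h replicate 1 or the 48 h replicate 2 and 1235 without the 48 h replicate 1. AGP30, ARP1, FUT6 and RGF2 had 0 UMI in both 24 h samples and 77.6 ± 64.9, 54.8 ± 38.2, 49.96 ± 25.9 and 41.1 ± 42.0 CPM at 48 h. For the cell cycle list the median log2 fold change was 2.08 with adjusted p = 1.38e-09 (rose), but adjusted p = 0.348 with an estimated correlation. There were 8 rises and 0 falls over all genes among 24 tested, and 16 and 0 adjusted over the list alone. The seed storage list fell with a median log2 fold change of -3.67 and adjusted p = 3.22e-07, but adjusted p = 0.348 with an estimated correlation. Of its 12 tested members, 0 rose and 4 fell over all genes, and 0 and 9 did so adjusted over the list alone. Jasmonate genes rose against other genes (median log2 fold change 2.46, adjusted p = 8.37e-07), but adjusted p = 0.157 with an estimated correlation. Among 8 tested, calls up numbered 6 and calls down 0 over all genes, and 7 and 0 adjusted over the list alone. LEA genes had a median log2 fold change of -0.94 (adjusted p = 1.80e-04, fell), but adjusted p = 0.398 with an estimated correlation. With 15 members tested, 0 rose and 3 fell over all genes, and 0 and 5 adjusted over the list alone. For the photosynthesis list the median log2 fold change was 1.01 with adjusted p = 0.0066 (rose), but adjusted p = 0.503 with an estimated correlation. There were 6 rises and 0 falls over all genes among 26 tested, and 7 and 0 adjusted over the list alone. The heat shock list rose with a median log2 fold change of 1.49 and adjusted p = 0.00867, but adjusted p = 0.348 with an estimated correlation. Of its 7 tested members, 2 rose and 0 fell over all genes, and 4 and 0 did so adjusted over the list alone. With a replicate block these lists had, in order, 18 up, 9 down, 7 up, 6 down, 13 up and 4 up over all genes. The low-oxygen, lipid mobilisation, ribosome, gibberellin and cell wall and touch and defence lists did not pass (adjusted p from 0.166 to 0.474). Median, mean and test differed in sign for gibberellin and cell wall (median 0.17, mean -0.59, test down).

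Across the 10189 genes tested in both data kinds, log2 changes of single-cell sums and bulk were correlated from 12 h to 24 h at Pearson r = 0.502 (Spearman rho 0.496) for intact and 0.498 (0.473) for dissociated bulk. From 24 h to 48 h the values were 0.789 (0.679) and 0.783 (0.705). Of genes called in intact bulk, 85.1% at the earlier and 89.7% at the later step had the same sign in cells, and of those called in dissociated bulk 84.0% and 94.9%. Genes are not independent replicates, so these are descriptions.

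Of the 15 deposited clusters, 6 could be named from marker genes and 9 could not. Cluster 9 was xylem-like, with 13 of 13 detected xylem markers peaking there. Cluster 13 was mesophyll-like (10 of 11 cotyledon mesophyll markers), cluster 4 dividing-like (7 of 10), cluster 14 root hair-like (6 of 6, with 3 root cap markers), cluster 15 phloem-like (6 of 12) and cluster 10 epidermis-like (6 of 11, with 3 of the stomatal lineage). Cells of cluster 13 had a median of 8.77 times the UMI of their samples' cells, so doublets, which were not called, are not excluded there. Those of cluster 10 had 0.34 times. Cluster 6 held 3 peaking epidermis and 3 stomatal lineage markers and stayed unnamed. For procambium at most 4 markers peaked in a cluster (cluster 9), and for root meristem and myrosin cells 2 (clusters 4 and 12). For cortex, endodermis, endosperm, shoot meristem and non-hair root epidermis it was 1. No seed coat marker was detected. The matrix held 1 marker each of cortex, non-hair root epidermis and seed coat, so these could not reach the 3 needed for a name.

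At 48 h the xylem-like cluster 9 held 0.149% (95% interval 0.031% to 0.434%) and 4.31% (3.74% to 4.93%) of the cells of replicates 1 and 2, and 0 cells at the earlier times. The mesophyll-like cluster 13 held 0.892% (0.529% to 1.41%) and 8.89% (8.09% to 9.74%), the root hair-like cluster 14 5.005% (4.095% to 6.05%) and 9.75% (8.91% to 10.6%), and the phloem-like cluster 15 1.49% (1.005% to 2.12%) and 7.78% (7.02% to 8.58%). The epidermis-like cluster 10 held 10.8% (9.44% to 12.2%) and 21.4% (20.2% to 22.6%). The dividing-like cluster 4 held 6.44% (5.41% to 7.60%) and 5.46% (4.83% to 6.15%). Its 7 peaking markers had 2750 UMI in its 385 cells of 48 h, but 1 in its 230 cells of 12 h and 6 in its 177 of 24 h, so the name rests on 48 h and is not used for the earlier cells. The same holds for cluster 14, with 0 marker UMI in its 72 cells of 24 h. Intervals cover counting error only, and of those above only cluster 4's overlapped. At 24 h cluster 1 held 71.1% and 11.4% of cells in replicates 1 and 2, and cluster 7 3.87% and 40.5%.

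**Figure D3:**
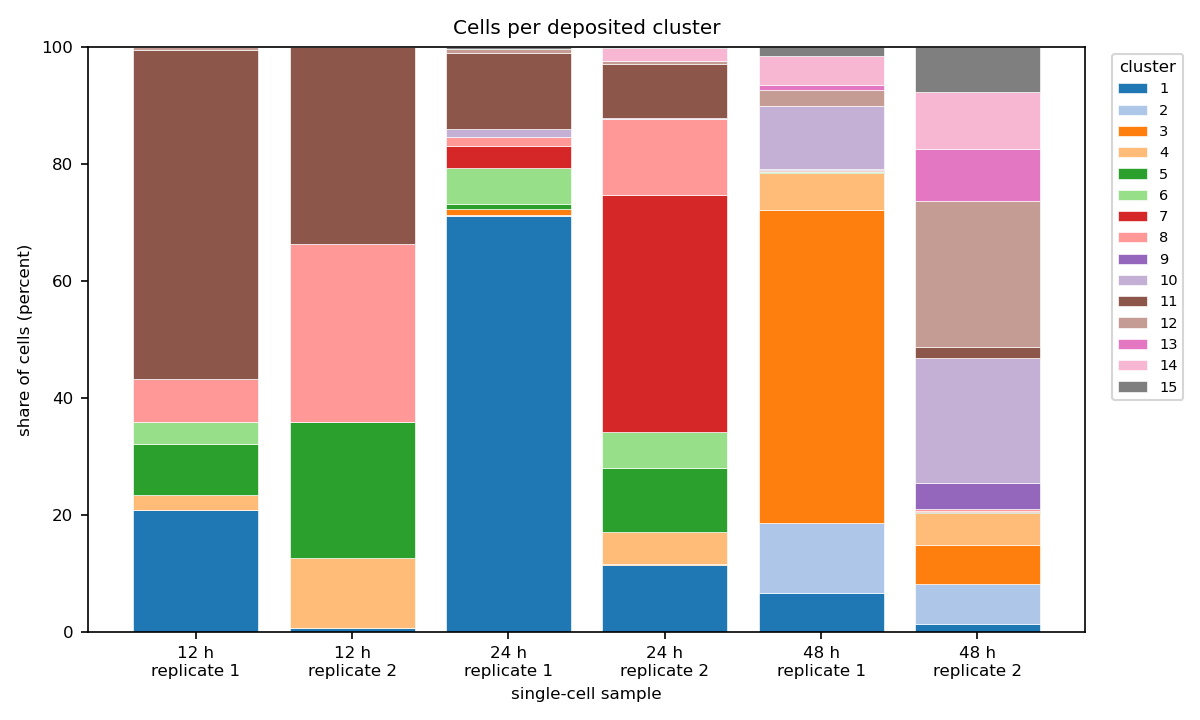
Share of cells in percent (vertical axis) in each of the 15 deposited clusters, stacked for the 6 single-cell samples. At 24 h cluster 1 held 71.1% and 11.4%.

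Within single clusters, 1 cluster per step had at least 20 cells in all 4 samples, and neither was named. In cluster 11 from 12 h to 24 h edgeR called 0 of 2813 genes (287 at an unadjusted p under 0.05), DESeq2 called 3 and the fit with a replicate block 147, and the edgeR count was 269 without the 12 h replicate 1, 13 without the 24 h replicate 1 and 8 without the 24 h replicate 2. In cluster 1 from 24 h to 48 h edgeR called 62 of 4528 genes, 60 up and 2 down, against 116 by DESeq2 and 207 with the block. There the count was 9 without the 24 h replicate 1, 1 without the 24 h replicate 2, 634 without the 48 h replicate 1 and 112 without the 48 h replicate 2.

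The last question was which genes the single-cell matrix held, since it held 56.6% of those tested in bulk by a rule not given. The list most changed by dissociation was nearly missing from it. Of 15 detoxification genes, 2 were present (PRX33 and PRX71, named after the values were seen), and all 12 seed storage and 26 of 30 photosynthesis genes were, against 8 of 19 ribosome and 4 of 10 endodermis genes, with no member called in 1 direction at all times. Of genes with a mean of at least 50 CPM that were called in 1 direction at all 3 times with a log2 change of at least 1.5, 0 of 207 were in the matrix (exact 95% upper limit 1.77%). At that level 1132 of 2135 genes called at no time were present (53.0%).

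**Figure D4:**
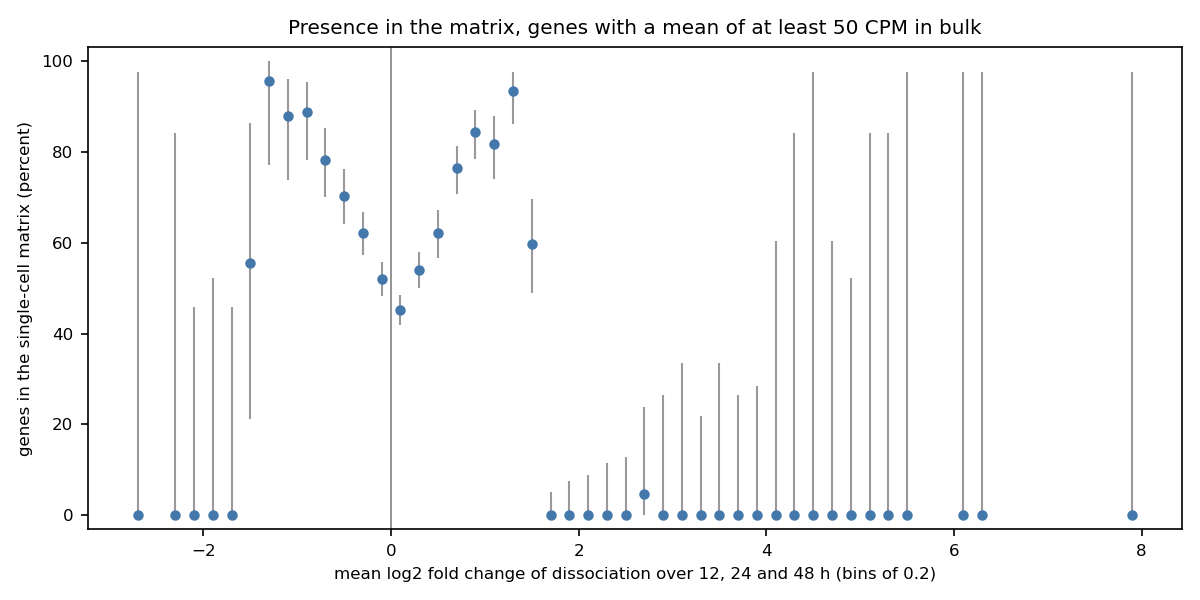
Share of genes with a mean of at least 50 CPM in bulk that were present in the single-cell matrix (vertical axis, percent, with exact 95% intervals) in bins of 0.2 of the mean log2 effect of dissociation over the 3 times (horizontal axis). The share was 45.2% between 0 and 0.2, 93.3% between 1.2 and 1.4 and 59.6% between 1.4 and 1.6, and beyond 1.6 the matrix held 1 of 326 genes, while outer bins hold few genes.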

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

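Tests of the missing genes, of sequencing depth, of the spread of the mixing test and of other splits of the samples were chosen after the results were seen, while those of mixing itself, of a label swap and of the 24 h single-cell samples were written down before their results.

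The dissociation effect differed between neighbouring times for 10 genes and 11 pathway lists, by a test of the difference itself, but with an estimated correlation none of the lists passed (adjusted p from 0.345 to 0.715). Between 12 h and 24 h the log2 difference was -3.40 for AT5G22140 (adjusted p = 0.0444, n = 3 per group). Between 24 h and 48 h, with 2 dissociated libraries at 48 h, it was 2.66 for AT1G49000 (adjusted p = 0.0485), 2.40 for SKP2B (0.0487), 1.97 for ABI5 (0.00524), 2.03 for AT3G14880 (0.0183), 1.71 for AT4G23050 (0.0183), 2.54 for LOG7 (0.0272), -2.58 for TBL21 (0.0272), -1.70 for UGT78D2 (0.00524) and 1.84 for AT5G49700 (0.0272). The genes other than ABI5, LOG7 and UGT78D2 were named after their values were seen. Fitted on the compared groups alone, edgeR called 1 other gene, and not AT5G22140, between 12 h and 24 h, and 0 genes between 24 h and 48 h.

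Among lists, the median differences between 12 h and 24 h were -1.33 for detoxification, -1.40 for low oxygen, -0.35 for ribosomes and -0.27 for touch and defence. Between 24 h and 48 h they were -0.64 for the cell cycle, 0.94 for heat shock, 0.67 for LEA proteins, -0.53 for low oxygen, 0.66 for photosynthesis, 0.88 for seed storage and -0.34 for touch and defence.

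Other splits of the 12 libraries of 12 h and 24 h into groups of the same makeup gave at least 1 call in 3 of 40 cases, the real one included (real 1, highest other 4158). The 2 other splits put all 3 dissociated libraries of 12 h into 1 group with only 1 of 24 h, so they follow the dissociation itself, a structure of the samples, and chance is not excluded for the single gene. For dissociation at 12 h and 24 h and for the steps from 12 h to 24 h and, in intact seeds, from 24 h to 48 h, the splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real counts there were 8679, 2987, 3150, 4481 and 7673, as large in 1 split each, and the highest other was 0.

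Abundant genes with a strong response to dissociation were missing from the single-cell matrix, while 76.3% of 845 genes called at all times with a smallest log2 change of 0.5 to 1 were present. Of genes of at least 50 CPM called at all 3 times with changes of at least 1.5, 0.0% were present, against 53.0% of genes called at no time, where a share of over 60% had been set, so the bound for removal by response was missed and that explanation may hold but stays open. Too few transcripts was argued against, since of genes of at least 100 CPM in dissociated bulk that rose by at least 1.5 at all times 0.0% were present (0 of 191) against 53.3% of uncalled ones. At any CPM, 12.1% of 461 that rose and 30.7% of 166 that fell by as much were present. No biological explanation was tested.

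The first dissociated replicate carried a smaller effect at 12 h and 24 h, with slopes of 0.617 and 0.586 on the mean effect against 0.845 to 1.29 for the others. RNA of intact material mixed in was argued against as the whole cause at 24 h, where the fraction of the effect differed by 0.485 between genes that rose (0.258) and fell (0.743), and between replicates 2 and 3 by up to 0.0179, but may hold at 12 h, where it differed by 0.3755 against up to 0.428 between the others, or, on genes called at 48 h, by 0.397 against up to 0.28, past the bound of 0.2 by less than these spreads. Low depth was argued against at 24 h by 20826489 counts (20.8 in units of 1e+06), the most in its group, and stays open at 12 h, where its 16068745 counts (16.07 in those units) were the fewest of all 17 libraries. A swap with an intact library was argued against by the largest shift of such a library towards the dissociated ones, 0.0831. A weaker or shorter treatment of that replicate stays open, untested.

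The pair of single-cell samples of 24 h differed in makeup and in plastid RNA. Depth per cell was argued against as the whole cause, since cluster 1 held 88.6% of 378 and 26.9% of 699 cells with 1000 to 3000 UMI, a 3.30-fold difference, though a smaller one than over all cells (71.1% and 11.4%), so depth may be part of it. Free plastid RNA in all cells of replicate 1 may hold and stays open, since an equal added share raises the ratio of shares least where the share is high, so the bound set beforehand was wrong, and replicate 1 was higher in all 4 clusters, with ratios from 1.26 to 2.77 and by 1.24 to 2.13 percentage points. Cells of the replicates also carry different barcode prefixes, and a batch difference cannot be told apart from one between seed lots. No biological explanation was tested.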

How the results depend on the processing

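The settings that left out both dissociated libraries numbered 1, the block in the list tests and all settings for single clusters were chosen after the data were seen. Of values for named genes, 4687 kept direction and side of the threshold, 355 lost the call, 52 gained one and 1 reversed. HSP17.6II from 24 h to 48 h in dissociated material went to -0.17 (adjusted p = 0.949) without dissociated 48 h replicate 2, in a range from -0.17 to 4.22 over left-out libraries, and the cause was not tested.

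With a fold of at least 2 added, counts of calls were 5162 and 1807 for dissociation at 12 h and 24 h, 1598 and 2434 from 12 h to 24 h in intact and dissociated material, and 4383 from 24 h to 48 h in intact seeds, and 1239 genes were shared over all times, which follows from the stricter rule. Fits on the compared groups alone gave 1527 from 12 h to 24 h in dissociated material and 0 for the difference of effects between 24 h and 48 h. Without a filter the differences of effects had 10 and 30 calls, sums of cells from 12 h to 24 h had 4, cluster 1 had 153 and cluster 11 had 30. DESeq2 called 309 and 300 for the differences, 260 and 1459 in sums of cells, 116 in cluster 1 and 3 in cluster 11. RLE scaling gave 4 for the difference between 24 h and 48 h. For these the cause was not tested.

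With a replicate block the differences of effects had 3 and 20 calls, sums of cells 243 and 3217, cluster 1 207 and cluster 11 147. With both dissociated libraries numbered 1 left out, dissociation at 24 h had 5421 calls and the differences 828 and 35. Adding the replicate block gave 6210, 2098 and 146. The cause was not tested.

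Leaving out 1 library in turn gave 6208 to 9823 calls for dissociation at 12 h, 1303 to 4527 at 24 h and 2915 to 5735 at 48 h, 1795 to 2358 and 2714 to 6023 from 12 h to 24 h in intact and dissociated material, and 5919 to 6844 and 1624 to 2759 from 24 h to 48 h. The differences of effects ranged from 0 to 1208 and from 2 to 43, sums of cells from 0 to 0 and from 0 to 1235, cluster 1 from 1 to 634 and cluster 11 from 0 to 269. Where 1 sample was left in a group, it is assumed to vary like the others.

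Of 61 calls in 130 tests of pathway lists (cell type lists are not in these totals), 5 held with an estimated correlation, 61 were called with RLE (1 lost, 1 gained), 64 with the block (1 lost, 4 gained) and 61 without the first dissociated libraries (6 lost, 6 gained). Correlations of cells and bulk over genes not called for dissociation were 0.536, 0.518, 0.802 and 0.8005, and Spearman values that moved were 0.473, 0.679 and 0.705.

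Tests within a named class and their alternative of 50 cells were not run, since no named class had enough cells, nor were other cluster resolutions, as clusters were deposited, nor another pseudocount, as the matrix holds counts. At the observed spread, changes of a log2 of 1 were recovered for 35.8% and 28.4% of simulated genes for dissociation at 12 h and 48 h and for 7.46% in the difference of effects.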

Other observations

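The test of the mean effect of dissociation was chosen after the data were seen, as was every value here. Membership in the single-cell matrix was looked at by 8 measures of the effect in 4 bands of level, and the mean log2 effect over the 3 times gave the sharpest edge, with bin limits set afterwards. Among genes of at least 50 CPM, 1 of 326 with a mean of at least 1.6 was present, PAL1 (AT2G37040, mean 2.74), and 0 of 20 with a mean of -1.6 or lower, against 95.5% between -1.4 and -1.2. This is a description, with no test of its own.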
